A study of Homo sapiens with 6 samples.

How the data were processed

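RNA-seq was measured in 6 libraries of Hs766T, an established human pancreatic ductal adenocarcinoma line derived from a lymph node metastasis. Total RNA was taken from 3 samples of cells overexpressing DDX18 and from 3 samples of control cells that the labels call plvx. Libraries were made with a SMARTER mRNA-seq kit, per the labels' protocols. The series describes the 3 libraries of each group as repeats of the sequencing, and nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

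One table of 58302 genes was deposited, with a count and an FPKM column for each library. The counts are raw counts per gene as the authors deposited them, whole numbers that sum to between 15911875 and 16207995 per library. The other columns hold FPKM per the file headers, as the authors deposited them. In 9997 genes with at least 100 counts in every library the FPKM equalled the count over one length per gene and the total of the count column, with a largest relative spread of that length over the libraries of 9.12e-06. That length was on median 1.56 times the merged exon length of the gene in GENCODE 29, so FPKM was compared between libraries only, never between genes. The aligner, the counter and the strand setting are not given in the sources used here. Reads from a gene and from an overlapping or antisense gene therefore may not be separable, and a DDX18 count may hold reads of both the introduced and the resident gene.

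The submitters' processing notes name the mouse builds GRCm38 and mm10. The table itself holds human Ensembl gene identifiers. Of these, 58039 occur in GENCODE 29, and 56604 of them (97.5%) have the start and end that GENCODE 29 gives on GRCh38. Coordinates are printed as the file gives them and were read as GRCh38. In 27 rows the gene symbol had been turned into a calendar date, and the symbol was restored from the gene identifier.

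Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 15144. Library sizes were scaled by TMM, and the quasi-likelihood F-test compared the groups with no further covariate. P-values were adjusted by Benjamini and Hochberg over the genes tested, with 0.05 as the threshold. Every adjusted p of a single gene below is from this test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. Values per library are CPM, counts over the library size after TMM scaling. The replicate spread had a common coefficient of variation of 15.9%. The 3 libraries of a group differed by far more than counting noise (a chi-square of 12.9 to 20.6 per degree of freedom for the pairs), so none was counted as a repeat deposit of another. For genes with many counts the precision is set by this spread and by 3 libraries per group rather than by depth. For genes with few counts, such as BRCA2 with 29 to 92 per library, counting noise limits it as well.

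The 30 gene lists were fixed before the data were examined, as were the design, the rule for named genes and the alternatives, except those stated below. Members were matched through the Ensembl identifier to current symbols. The ones of signalling, growth and stress hold AP-1 and immediate-early genes, MYC targets, p53 targets, interferon, NF-κB, unfolded protein, heat-shock and hypoxia genes. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists. The same test with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were alternatives. The text names DDX18, and up to 10 higher and 10 lower genes with the largest fold change among those past the threshold with a group mean of at least 5 CPM and groups that do not overlap. It also names up to 4 members of each list discussed that passed the threshold, or the member with the smallest p where none did, and EZH2, MYC, CDH1 and VIM whatever their values. A gene that this rule names is not reported here. Other list members are named as examples and were chosen after their values were seen.

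The edgeR step was tested on simulated counts for these 15144 genes with 200 genes changed in each of 2 runs. It recovered 17.2% of 1.5-fold, 59.0% of 2-fold and 82.6% of 3-fold changes, and 9.8% of its calls were false. When the 21 tested members of the AP-1 list were raised 1.25-fold in simulated counts, camera called that list alone. The simulated genes were drawn independently of each other, so this run cannot show how often lists of correlated genes are called falsely. Alternatives were size factors as in DESeq2, no scaling beyond totals, upper-quartile scaling, no expression filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, removal of the 10 most counted genes and leaving out each library. Robust quasi-likelihood priors, and the histone list without H1F0, which is not a replication-dependent histone, were added after seeing the data. Overlap of exons was taken from GENCODE 29 with bedtools 2.31.1.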

Results

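The transcriptome of Hs766T pancreatic cancer cells was compared between cells overexpressing DDX18, a nucleolar DEAD-box RNA helicase of ribosome assembly, and control cells, with 3 libraries each. The series asks how high DDX18 expression affects other molecules in these cells. Total counts lay between 15911875 and 16207995 per library, and 22132 to 23286 genes had at least 1 count. The share of counts on the mitochondrial genome was 2.44% to 2.75% in the DDX18 libraries and 2.67% to 3.15% in the controls. Libraries resembled each other as closely across groups as within them. Pearson correlations of log2 CPM over genes were 0.98 to 0.984 both within and between the groups.

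DDX18 rose in the cells made to overexpress it. The gene (ENSG00000088205, chromosome 2, 117814650 to 117832379, plus strand) measured 187.1 ± 10.2 CPM with DDX18 overexpression and 90.0 ± 7.98 CPM in the controls (SD, n = 3). The rise was 2.08-fold, with a 95% confidence interval of 1.81 to 2.39 and an adjusted p of 0.00982 (edgeR). All 3 overexpressing libraries lay above all 3 controls, in the direction the labels give. The fold was stable when single libraries were left out (log2 fold change 1.00 to 1.12), but the adjusted p was above 0.05 without DDX18 replicate 2 (0.0544) and without control replicate 2 (0.0643).

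Besides DDX18, 7 of the 15144 genes tested passed the threshold, 3 of them higher and 4 lower. Splits of the libraries that mixed the groups gave up to 10 such calls. Of the 7 genes, 5 had counts at 2 separate levels, a pattern that 247 genes shared, mostly along other divisions of the libraries. An effect of DDX18 on the 7 genes is therefore not established. MAP1S, a microtubule-associated protein with a part in autophagy, rose most, from 22.3 ± 1.81 to 78.3 ± 2.22 CPM (3.51-fold, adjusted p = 0.000969). CDKN2A, the locus of cell-cycle inhibitors upstream of RB and p53, rose from 213.3 ± 28.7 to 471.9 ± 17.3 CPM (2.21-fold, adjusted p = 0.0131). SLC39A1, a zinc importer, rose from 103.2 ± 4.08 to 177.8 ± 17.7 CPM (1.72-fold, adjusted p = 0.0496). Of the genes that fell, HIGD1A, a small inner mitochondrial membrane protein induced by hypoxia, went from 84.0 ± 1.94 to 33.7 ± 5.67 CPM (2.49-fold lower, adjusted p = 0.0218). SYNGR2, a vesicle membrane protein, fell from 185.7 ± 12.7 to 83.4 ± 7.75 CPM (2.23-fold lower, adjusted p = 0.00982). CANX, the calnexin chaperone of the endoplasmic reticulum, fell from 1027 ± 90.4 to 492.2 ± 2.17 CPM (2.09-fold lower, adjusted p = 0.00766). TGIF1, a homeobox corepressor in TGF-β signalling, fell from 29.8 ± 0.78 to 15.96 ± 1.15 CPM (1.87-fold lower, adjusted p = 0.0398). Values are means ± SD of 3 libraries, and the log2 fold changes of the 8 called genes had standard errors of 0.076 to 0.127.

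The calls of MAP1S and CANX held whichever library was left out. SYNGR2 had an adjusted p of 0.0576 without DDX18 replicate 3 and 0.0643 without control replicate 2. CDKN2A had 0.0683 without DDX18 replicate 2, 0.0576 without DDX18 replicate 3 and 0.125 without control replicate 2. HIGD1A kept its call only without DDX18 replicate 1 (0.0576 to 0.125 in the other 5 cases), SLC39A1 only without DDX18 replicate 3 (0.131 to 0.207), and TGIF1 in none of the 6 (0.0849 to 0.207). The number of changed genes was 14 without control replicate 1, 3 without control replicate 2, and 5 without DDX18 replicate 2 or 3.

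**Figure D1:**
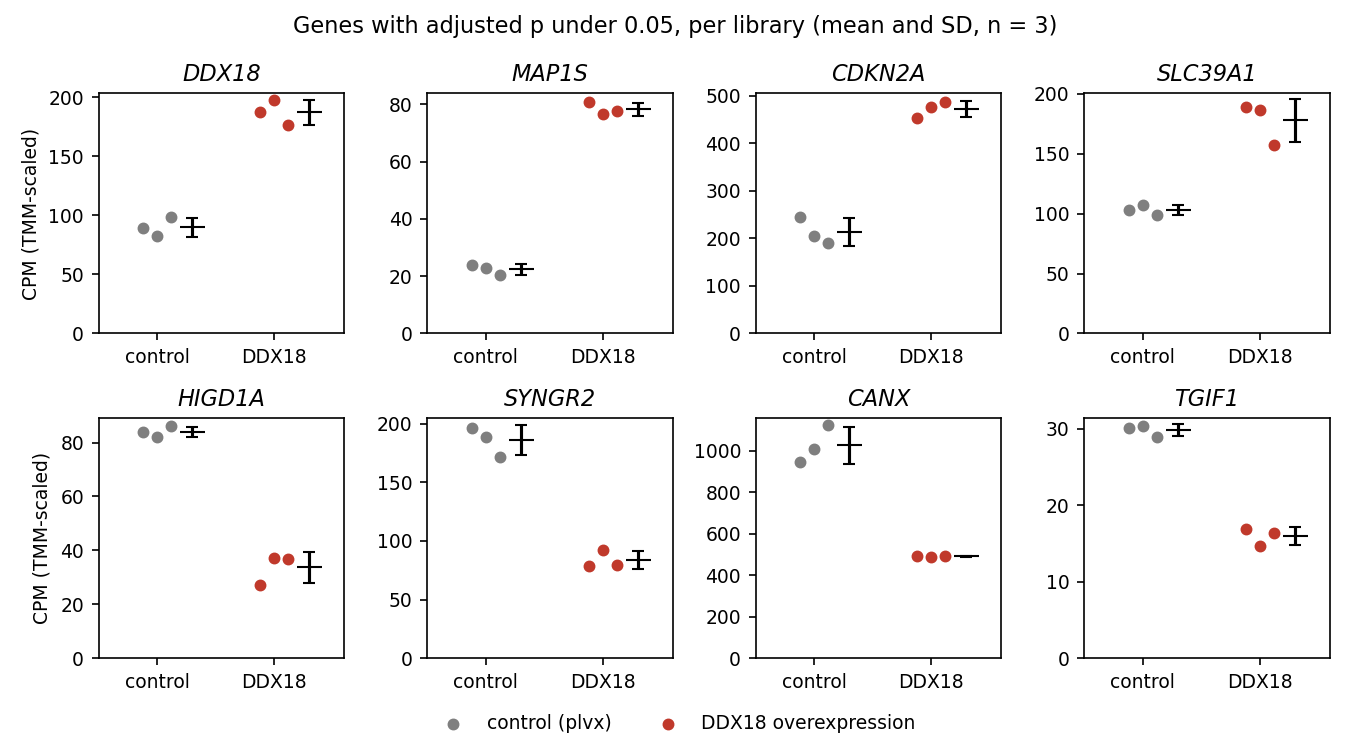
CPM after TMM scaling (linear axes from 0) of the 8 genes with an adjusted p under 0.05, one panel per gene; each point is 1 library, grey for control and red for DDX18 overexpression, and the black mark is the group mean with its SD (n = 3). In each panel the 3 libraries of one group lie apart from the 3 of the other, as for MAP1S with means of 78.3 and 22.3 CPM.

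The 7 genes lie on 7 chromosomes. MAP1S (ENSG00000130479) spans 17719242 to 17734516 on chromosome 19. CDKN2A (ENSG00000147889) spans 21967753 to 21995301 on chromosome 9, and an antisense gene that overlaps its exons, CDKN2B-AS1, held 26.7 mean counts against 7559.7 for CDKN2A in the DDX18 libraries. SLC39A1 (ENSG00000143570) spans 153959099 to 153968184 on chromosome 1 and overlaps CREB3L4, a coding gene on the other strand with 247.0 and 244.7 mean counts in the DDX18 and control libraries. HIGD1A (ENSG00000181061) spans 42784298 to 42804531 on chromosome 3. SYNGR2 (ENSG00000108639) spans 78168558 to 78173527 on chromosome 17. CANX (ENSG00000127022) spans 179678628 to 179730925 on chromosome 5. TGIF1 (ENSG00000177426) spans 3411608 to 3459978 on chromosome 18.

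Of the 8 genes, 4 were higher and 4 lower, and 6 had changed at least 2-fold. A further 4 genes had an adjusted p between 0.05 and 0.1, among them SUOX, the mitochondrial sulfite oxidase (30.7 ± 2.03 against 10.7 ± 2.83 CPM, adjusted p = 0.0647), and HMGB1, an abundant chromatin protein (99.3 ± 6.59 against 166.7 ± 17.8 CPM, adjusted p = 0.0805). Both were chosen after their values were seen. At an unadjusted p under 0.05 there were 862 genes, 5.7% of those tested. The other 9 splits of the libraries into 3 against 3 gave 438 to 1338 such genes by the same test. The groups did not overlap in 1748 genes (11.5%), where chance gives 10%. DESeq2 called 40 genes, 18 higher and 22 lower, with all 8 among them. Counts of several of these genes sat at separate levels without intermediate values, a property that 247 genes shared, most of them along other divisions of the libraries.

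**Figure D2:**
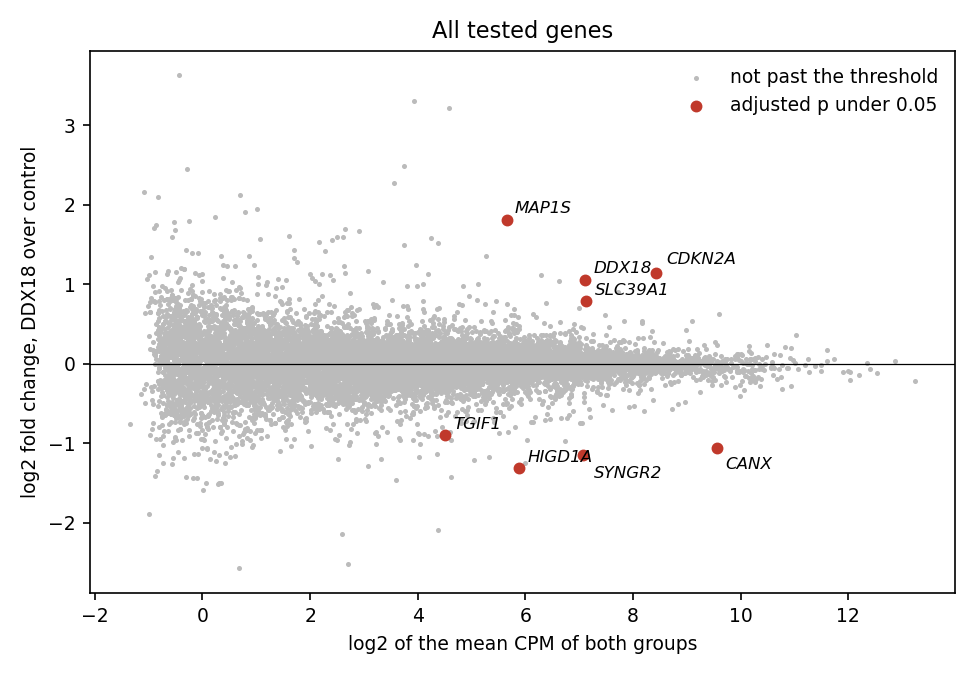
Log2 fold change (DDX18 over control) against log2 mean CPM of both groups for the 15144 genes tested; red points are the 8 genes past an adjusted p of 0.05, with their symbols, and grey points the rest. The called genes lie between -1.32 (HIGD1A) and 1.81 (MAP1S) on the log2 scale, and some grey points with larger fold changes did not pass.

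EZH2, the methyltransferase of Polycomb repressive complex 2, measured 81.1 ± 1.9 CPM with DDX18 and 87.3 ± 7.9 CPM in controls (adjusted p = 0.917). None of the 12 tested subunits of that complex passed the threshold, and the one with the smallest p was MTF2 (15.2 ± 3.23 against 18.6 ± 2.23 CPM, adjusted p = 0.875). VIM, the mesenchymal intermediate filament, was at 910.3 ± 53.4 and 906.7 ± 56.1 CPM. CDH1, the epithelial cadherin, was near 2 CPM in both groups (2.23 ± 0.257 and 2.06 ± 0.281). MYC measured 51.6 ± 43.8 and 33.1 ± 39.4 CPM (adjusted p = 0.963), and its libraries ran from 8.54 to 96.5 CPM irrespective of group.

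In the 30 gene lists, 541 different genes were tested. None of them passed the edgeR threshold over all genes. At an unadjusted p under 0.05 there were 63, and DESeq2 called 2 of them, EGR1 and the ATP synthase subunit ATP5F1A, while limma-voom called 0. As sets, 5 of the 30 lists were called by camera with the preset correlation, 2 of them higher and 3 lower with DDX18, and 4 were called once a gene that does not belong in the histone list was left out. None of the 5 was called with an estimated correlation or by fry. The estimated setting raised p even where the estimated correlation was below the preset 0.01. In the mesenchymal list that correlation was -0.01, and the unadjusted camera p was 0.0514 against 0.0121 with the preset one. A call lost under that setting therefore does not by itself show that the genes of a list vary together. Camera called 2 lists without DDX18 replicate 1 or control replicate 3, and 3 without DDX18 replicate 3.

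The AP-1 and immediate-early list, transcription factors and phosphatases that respond within minutes to growth factor signals, was the list furthest apart. Of its 21 tested members, 20 had a positive fold change, with a median log2 fold change of 0.30 (camera adjusted p = 3.13e-08). That call was lost with an estimated correlation of 0.06 (adjusted p = 0.322) and by fry (adjusted p = 0.0999). Adjusted over the list alone, 3 members passed, namely EGR1, DUSP1 and ATF3, against 0 over all genes. EGR1, a zinc-finger factor, was at 22.9 ± 3.1 CPM with DDX18 and 11.4 ± 2.25 CPM in controls (2.01-fold, adjusted p over all genes = 0.428). DUSP1, a MAP kinase phosphatase, was at 89.9 ± 4.04 and 69.9 ± 3.14 CPM (1.29-fold, adjusted p over all genes = 0.539). ATF3 was at 17.3 ± 2.7 and 10.5 ± 2.08 CPM (1.65-fold, adjusted p over all genes = 0.734). JUNB (68.0 ± 3.15 against 58.3 ± 4.74 CPM) and JUN (30.04 ± 1.5 against 25.0 ± 0.315 CPM) did not pass over the list. FOSL2 was the member with a negative fold change, and its value rested on DDX18 replicate 1 (61.9 CPM against 172.7 to 191.3 CPM in the other 5 libraries). The list's median lay above its mean over libraries in each DDX18 library (0.10 to 0.24 log2) and below it in each control (-0.21 to -0.10). The call held in all 16 alternative settings of the preset test (adjusted p 2.29e-09 to 2.92e-05). Of the other 9 splits of the libraries into 3 against 3, 2 also called this list (adjusted p = 0.00134 and 0.0325).

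**Figure D3:**
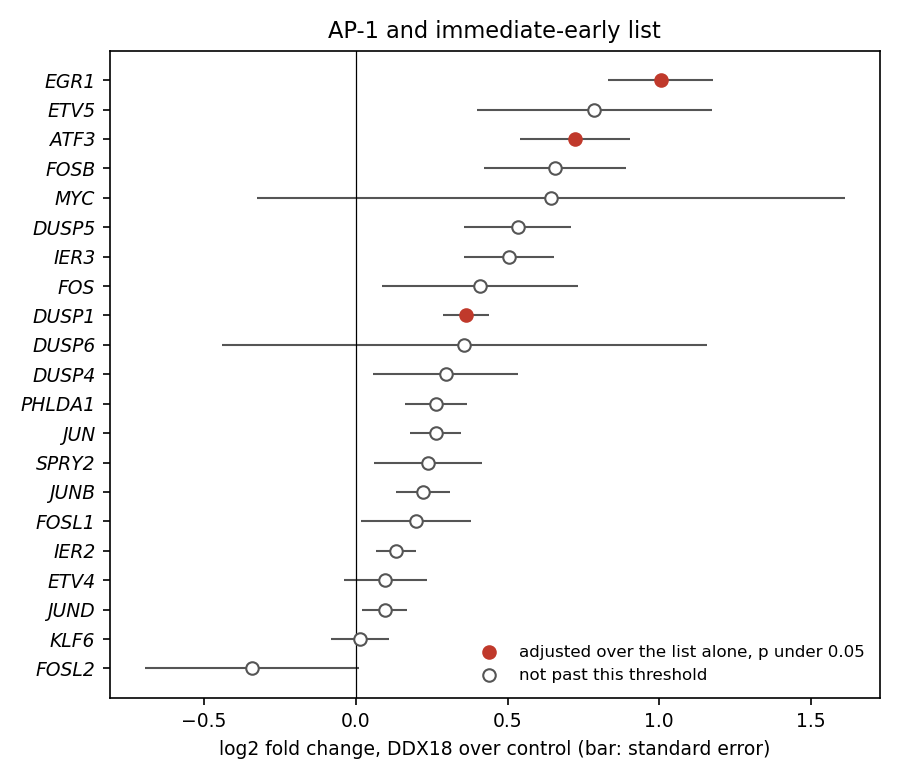
Log2 fold change (DDX18 over control) with its standard error for the 21 tested members of the AP-1 and immediate-early list; filled red points passed an adjusted p of 0.05 over the list alone, open points did not. All points except FOSL2 lie above 0, and EGR1 is furthest at 1.00.

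The 13 protein-coding genes of the mitochondrial genome were lower as a list, with a median log2 fold change of -0.21 (camera adjusted p = 4.15e-05), and each of the 13 had a negative fold change. These genes vary together (estimated correlation 0.558), and adjusted p = 0.777 with an estimated correlation. Adjusted over the list alone, 4 passed, MT-ATP6 (531.5 ± 43.6 against 680.8 ± 67.6 CPM), MT-ND2 (948.4 ± 37.8 against 1198 ± 145 CPM), MT-ND3 and MT-CO3, against 0 over all genes. The median relative level of the list was 0.27 log2 in control replicate 2, 0.10 in control replicate 3 and -0.04 in control replicate 1, and -0.15 to -0.06 in the DDX18 libraries. Without control replicate 2 the median was -0.17 (adjusted p = 0.028). Of the other 9 splits of 3 against 3 libraries, 2 also called this list (adjusted p = 0.00013 and 0.0109), with an absolute median of 0.20 in the first. The nuclear-encoded subunits of the respiratory chain and ATP synthase were not called as a list (adjusted p = 0.636), and ATP5F1A was at 378.4 ± 56.7 against 539.5 ± 24.1 CPM (adjusted p = 0.539 by edgeR over all genes) and passed when adjusted over the list alone.

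In the G2 and mitosis list, 27 of 30 members had a negative fold change with a median of -0.06 on the log2 scale (camera adjusted p = 0.0176, but adjusted p = 0.777 with an estimated correlation). Its median relative level overlapped between the groups: it was -0.035, 0.009 and 0.12 log2 in control replicates 1, 2 and 3, and -0.032, -0.001 and -0.121 in DDX18 replicates 1, 2 and 3. CENPF, a kinetochore protein, was at 87.9 ± 3.12 against 113.7 ± 17.4 CPM. In the DNA damage and repair list, 17 of 24 members had a negative fold change, with a median of -0.14 (camera adjusted p = 0.0329, but adjusted p = 0.73 with an estimated correlation). BRCA2 was at 2.04 ± 0.297 against 4.19 ± 1.29 CPM, and ATR at 19.5 ± 0.104 against 24.9 ± 2.85 CPM. In the list fixed for replication-dependent histone genes, 10 of 14 members had a positive fold change, with a median of 0.16 (camera adjusted p = 0.0329, but adjusted p = 0.777 with an estimated correlation). That list holds H1F0, a linker histone made independently of replication (247.4 ± 5.99 against 215.1 ± 16.5 CPM). Without it 9 of 13 members had a positive fold change, with a median of 0.12, and the list was not called (adjusted p = 0.0713). HIST1H2BD was at 10.9 ± 0.744 against 8.24 ± 0.665 CPM. No member of these lists passed an adjusted p of 0.05, over all genes or over the list alone. Leaving out a library ended the G2 and mitosis call in 3 of 6 cases: adjusted p = 0.0524 without DDX18 replicate 1, 0.178 without DDX18 replicate 3 and 0.244 without control replicate 3. The DNA repair call ended without DDX18 replicate 1 (0.0846) or 3 (0.211) and without control replicate 2 (0.115) or 3 (0.166), and the histone call without DDX18 replicate 1 (0.75, with the median at -0.02) or control replicate 1 (0.062), 2 (0.109) or 3 (0.0799). With no expression filter the adjusted p was 0.0546 for G2 and mitosis, 0.095 for DNA repair and 0.156 for histones, and DNA repair had 0.127 with the stricter filter and 0.0635 on log2(FPKM + 1).

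Genes of ribosome assembly, the process DDX18 takes part in, were not called. Of 40 members tested, 20 had a positive and 20 a negative fold change, with a median of 0.00 (camera adjusted p = 0.821). NOP58, a core protein of box C/D ribonucleoprotein particles, had the smallest p (39.4 ± 7.49 against 51.3 ± 4.25 CPM, adjusted p = 0.841). The cytosolic ribosomal proteins divided 21 to 21, with a median of 0.00 and RPL11 at 821.7 ± 98.7 against 698.6 ± 40.8 CPM. Many ribosomal protein genes share reads with processed pseudogenes, so their single values are uncertain. The other 29 tested DEAD-box helicases had 14 positive and 15 negative fold changes, and DDX56 was at 179.9 ± 8.61 against 207.3 ± 3.35 CPM.

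The remaining tumour and stress lists were not called either, each with a camera adjusted p of 0.0603 or more. The mesenchymal list came nearest (14 of 21 members with a positive fold change, median 0.08, adjusted p = 0.0603), led by CYR61, a matricellular protein (413.5 ± 6.64 against 345.1 ± 32.5 CPM). It was called under the stricter filter (adjusted p = 0.0162), with limma-voom (0.0331), without DDX18 replicate 2 (0.037) and without control replicate 2 (0.046), but adjusted p = 0.73 with an estimated correlation. Among epithelial genes CLDN7 was at 28.97 ± 2.17 against 20.7 ± 4.51 CPM. Of 24 genes of the classical pancreatic tumour subtype only 4 could be tested, and GATA6, a transcription factor of that subtype, was at 13.1 ± 1.34 against 9.71 ± 0.504 CPM and passed over the list alone. TNS4 had the smallest p of the basal-like list (18.8 ± 0.597 against 23.5 ± 2.84 CPM). S-phase genes were led by RRM2, a ribonucleotide reductase subunit (96.2 ± 38.4 against 161.9 ± 22 CPM), and p53 targets by PLK3 (7.99 ± 0.813 against 6.05 ± 0.559 CPM). ISG15 led the interferon list (19.4 ± 1.72 against 15.7 ± 0.271 CPM), RELB the NF-κB list (6.01 ± 0.86 against 8.17 ± 0.479 CPM) and HLA-C the antigen presentation list (215.4 ± 54.8 against 141.1 ± 2.57 CPM). HLA-C reads can be shared with other class I genes. Metabolic and chaperone lists were led by PKM (2353 ± 154 against 1841 ± 371 CPM), HSP90B1 (230.3 ± 14.7 against 273.2 ± 23.7 CPM), DNAJB1 (118.0 ± 9 against 133.6 ± 1.99 CPM) and DHCR7 (118.4 ± 4.02 against 153.5 ± 27.2 CPM). CCT5 led the MYC target list (1200 ± 71.2 against 1075 ± 78.2 CPM), and the list of TGF-β, WNT and Notch targets had a median log2 fold change of 0.05 (camera adjusted p = 0.636). None of the genes in this paragraph passed the threshold over all genes with all 6 libraries. HLA-C did without DDX18 replicate 2 (adjusted p = 0.0488). For HLA-C that library was at 152.3 CPM, near the controls (138.9 to 143.9 CPM), with DDX18 replicates 1 and 3 at 250.7 and 243.2 CPM.

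Markers of other cell types were mostly near or at 0. Of 73 markers of acinar, endocrine, fibroblast, immune and endothelial cells, 36 had no count in any library and 16 were expressed enough to test. None of the 16 was called by edgeR or DESeq2, 2 had an unadjusted p under 0.05, and no marker list was called by camera. Those 2 were COL1A1 (55.1 ± 3.17 against 66.8 ± 4.39 CPM) and PDGFRB (105.0 ± 2.27 against 91.6 ± 4.15 CPM), both genes of fibroblasts, with opposite signs. BHLHA15 was the 1 acinar marker that could be tested (1.96 ± 0.048 against 1.75 ± 0.533 CPM). PCSK1 led the endocrine markers (4.24 ± 0.32 against 5.36 ± 1.12 CPM), HBA1 the blood and immune markers (6.04 ± 0.909 against 7.48 ± 0.837 CPM), and ESAM the endothelial markers (84.8 ± 4.9 against 78.1 ± 8.72 CPM).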

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

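DDX18 kept its direction under all 18 alternatives, with a log2 fold change from 0.988 to 1.119. The 8 called genes were the same 8 under the DESeq2 size factors, no scaling beyond totals, upper-quartile scaling, the stricter filter and removal of the 10 most counted genes, and the median log2 fold change of all genes lay between -0.001 and 0.012 under the 4 scalings. With no expression filter 4 genes were called, 2 higher and 2 lower, with 28655 genes tested; the p-values of the 4 lost genes before adjustment rose as well. DESeq2 called 40 genes, 18 higher, 22 lower and 19 changed at least 2-fold, and the robust priors, chosen after seeing the data, called 7 higher and 12 in all. Both included the 8; the cause was not tested. Leaving out 1 library at a time gave 3 to 14 genes, 2 to 7 higher, 1 to 7 lower and 3 to 13 changed at least 2-fold, with 3 genes without control replicate 2, 14 without control replicate 1, and 5 without DDX18 replicate 2 or 3; DDX18 then ranged from 0.995 to 1.119 (log2). Only MAP1S stayed past the threshold under all 18 alternatives. CANX passed in 17, SYNGR2 and DDX18 in 15, CDKN2A in 13, HIGD1A in 11, and SLC39A1 and TGIF1 in 8. With the replicate number as a block 1 gene was called, 1 higher, 0 lower and 1 changed at least 2-fold (MAP1S), and DDX18 kept a log2 fold change of 1.06 with an adjusted p of 0.153. Libraries with the same number did not deviate together (correlations -0.043, 0.019 and -0.087), so the replicate block pairs nothing the data show, and 2 degrees of freedom were spent on it. The count of 5 called gene lists became 2 with no expression filter, 0 with an estimated correlation and 0 by fry, and 2 to 6 when 1 library was left out (2 without DDX18 replicate 1 or control replicate 3, 3 without DDX18 replicate 3). It became 4 without H1F0 in the histone list, an alternative chosen after seeing the data. Of 1273 further values of single genes and lists under the alternatives, 1202 stayed on their side of the threshold, 64 lost a call and 7 gained one, 4 of these the mesenchymal list, the others EGR1 and ATP5F1A with DESeq2 and HLA-C without DDX18 replicate 2. Only sign changes of called values were counted as reversals, a rule narrowed after such changes among uncalled values had been seen; 66 uncalled values changed sign. For lists the direction was that of the set test, which never turned for a called list, but the median of the histone list went from 0.16 to -0.02 without DDX18 replicate 1. Depth, 15911875 to 16207995 counts per library, differed too little to order the libraries, and 1.5-fold changes were mostly out of reach at this replicate spread. DESeq2 was not applied to the lists.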

Other observations

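The tests of unstable AP-1 members, of harvest handling, of 2-level genes along the groups, and of other splits for the lists and for DESeq2 were chosen after the results were seen, as were the limits that define a 2-level gene and an unstable member. Some keratin and surface genes, chosen after their values were seen, were measured as follows. KRT8 was at 2057 ± 350 with DDX18 and 1993 ± 255 CPM in controls, KRT18 at 855.8 ± 53.1 and 1046 ± 207 CPM, and KRT7 at 606.6 ± 88.6 and 602.5 ± 32.3 CPM. The receptor kinase AXL was at 266 ± 7.68 and 252.2 ± 12 CPM, and EPCAM, an epithelial adhesion protein, at 5.39 ± 1.08 and 7.05 ± 1 CPM. None of these 5 genes had an unadjusted p under 0.05 by edgeR, and none was called by DESeq2. Of the mesenchymal list, CYR61, CTGF (220.5 ± 8.38 against 180.1 ± 21.8 CPM), THBS1 (109.9 ± 8.04 against 94.3 ± 5.29 CPM), TWIST2 (34.9 ± 1 against 27.8 ± 2.77 CPM) and TNC had an unadjusted p under 0.05 and a positive fold change, and none passed over the list alone. GPD1L, a glycerol phosphate dehydrogenase relative, was at 28.6 ± 6.09 against 9.54 ± 1.66 CPM (adjusted p = 0.0664 by edgeR), and SPINK5, a serine protease inhibitor, at 198.1 ± 15.4 against 289.2 ± 19.4 CPM (adjusted p = 0.235). DESeq2 called both.

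Many abundant genes had counts at 2 separate levels that mostly did not follow the groups: 247 of 9997 genes with at least 100 counts in each library had a largest gap above 0.6 log2 and every other gap under 0.25, and in 146 of them 1 library stood apart, 22 to 27 genes for each of the 6 libraries. RPLP1, a protein of the ribosomal stalk, was at 845.4 CPM in control replicate 1 and at 1522 to 1584 CPM in the other 5 libraries, and RELA, an NF-κB subunit, had 994 and 1011 counts in DDX18 replicate 1 and control replicate 3 and 1975 to 2391 in the others. Simulated tables held 0.65 such genes on average, which argues against sampling noise at a replicate variation of 8.8%. Every simulated gene had that same variation, below the common 15.9% of the edgeR fit. Genes with a wider spread of their own were therefore not covered. Reads passing to an overlapping gene model could be seen only in the 129 genes that had an exon-overlapping gene. In 12 of these (4.9% of the 247) such a gene moved the opposite way by at least 0.5 of the gap. This argues against such passing for most of the genes, not for all. Counting that depends on several transcript models stays open, since 0.96% of genes with 1 annotated transcript were at 2 levels against 2.61% of the others, a ratio of 0.37 that lies between the bounds set for and against it (Fisher's exact test, two-sided p = 0.00216). No biological explanation was tested for the genes that do not follow the groups.

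The genes called between the groups may in part be such 2-level genes that fell along the groups. Of the 7 called genes other than DDX18, 5 met the 2-level definition (MAP1S, CDKN2A, SYNGR2, CANX and TGIF1), and these were the 5 genes besides DDX18 at 2 levels along the groups, where the other 9 splits of 3 against 3 libraries held 1 to 5 each. In the edgeR test the real split gave 8 genes and the highest other 10 (3 of the 10 splits gave at least 8, the real one included), and with DESeq2 the real split gave 40 and the highest other 68 (2 of 10 gave at least 40); 10 splits are too few for a share under 0.05. An effect of DDX18 stays open as well, since a true change would also give 2 levels. HIGD1A and SLC39A1 did not meet the definition, but its limits were chosen after the results were seen. Their calls held in only 11 and 8 of the 18 alternatives. Missing the definition therefore does not speak for an effect of DDX18 on these genes.

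The AP-1 and immediate-early list was higher with DDX18 by camera with the preset correlation, not with an estimated correlation (adjusted p = 0.322) or by fry (0.0999), and a few members with unstable counts were tested as the cause. MYC, FOSL2, FOS, ETV5 and DUSP6 were at 2 levels or spread over more than 1 log2 unit within a group. Without them the 16 remaining members had a median of 0.26. All 16 had a positive fold change, but FOSL2, the only negative member, was among those removed. With the preset correlation the unadjusted camera p was 8.88e-11 (1.04e-09 for all 21 members), which argues against the unstable members under that setting. With an estimated correlation the unadjusted camera p was 0.00521 (0.0107 for all 21 members). That value lies between the bounds set for and against this cause. So did the value for all 21 members, so under this setting the bounds could not judge the removal. Leaving out FOSL2, the only negative member, favours a lower p. Even so, the 16 remaining members kept a median of 0.26, and p rose in neither setting. This argues against the unstable members as the cause of the higher immediate-early genes. Handling of the cultures at harvest could also raise such genes and cannot be told apart from DDX18, as no record per library is held here; the heat-shock list had a median log2 fold change of -0.029, which bears on heat or proteotoxic stress only. The real split gave 5 called lists, which 1 of the 10 splits reached (the real one), and the highest other split gave 3. Without H1F0 in the histone list the real split gave 4, and the other splits were not run without it. The AP-1 list itself was called in 2 of the other 9 (camera adjusted p = 0.00134 and 0.0325), and 10 splits are too few for a share under 0.05. That DDX18 raises immediate-early transcripts in these cells is a hypothesis, found and tested on the same 6 libraries.

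Counts on processed pseudogenes made up 4.32% to 4.58% of each library. EEF1A1P5, a processed pseudogene, held 45460 to 53423 counts, against 36469 to 47403 for its parent gene EEF1A1.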
